A study of Mus musculus with 14 samples.

How the data were processed

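The labels give 14 libraries in 6 groups, formed by developmental stage (fetal or adult) and assay (CAGE, ATAC-seq or Hi-C), and each library was placed in its group by its title. The submitters' processing notes name the mouse genome build mm10 for all 3 assays. They name Bowtie2 for the CAGE libraries, Bowtie2, SAMtools and MACS2 for the ATAC-seq libraries, and Trim Galore and HiC-Pro for the Hi-C libraries. Tool versions are not given in the sources used here, and no values of these libraries were analysed here.

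The 1 processed table examined holds whole numbers per Entrez gene identifier, and its header names no unit, aligner, counter or genome build. Its 12 value columns were compared by name with the titles and descriptions of the 14 libraries, using Python 3.11.15. A match was counted where one name contained the other after case and separators were removed. No column matched, and all 12 columns were left out of every step, because a column that cannot be tied to a described library may belong to another experiment. Reading the abbreviation "c" as CAGE, or treating the fetal and adult columns as the described fetal and adult libraries, would have been a guess at the mapping.

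A test of fetal against adult gene counts and a test of gene lists had been planned before the data were examined. Neither test was run, since no library had values that could be assigned to it.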

Results

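The labels describe 14 mouse libraries of the C57BL/6J strain, prepared from small intestinal epithelial organoids, which are epithelial cells grown in a gel as hollow or budding structures. The organoids came from fetal epithelium or from adult crypts of the proximal small intestine, and all were untreated. CAGE, which sequences the capped 5′ ends of transcripts and so measures transcription start site usage, was represented by 3 fetal and 3 adult libraries. ATAC-seq, which measures the accessibility of chromatin to a transposase, was represented by 2 fetal and 2 adult libraries of cells sorted for the epithelial surface protein EpCAM. Hi-C, which measures contacts between genomic regions, was represented by 2 fetal and 2 adult libraries. The comparison this design implies is fetal against adult organoids within each assay.

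That comparison was not made here. The table used as input lists 27179 genes by Entrez identifier and has 12 columns of values, and its name describes it as RNA-seq, an assay that none of the 14 described libraries used. The column names combine fetal or adult with the abbreviations "ln" or "c", which the labels do not explain. Of the 12 columns, 0 matched the title or description of a described library, so no column was assigned to a library or a group. The titles place "rep" directly after the stage, where the column names place "ln" or "c". Neither name could therefore contain the other, and the lack of matches to titles does not show where the columns came from. Expression levels, depth per library, fold changes and tests between fetal and adult organoids are therefore not reported, and nothing is stated about the direction or size of any difference in transcription, accessibility or chromatin contacts.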

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

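No paired analysis was possible because no column of values was assigned to a described library. For the same reason no test was run under any setting for normalization, filtering, replicates left out or the correlation within gene lists. A looser rule for matching names used only the stage and the number, and also assigned 0 of the 12 columns. It counted a column only where the column matched 1 library that no other column matched. Each stage and number occurs under both "ln" and "c", so the looser rule could not have assigned any column and adds no support. The looser rule was chosen after seeing the data, and neither rule was planned in advance. Under the looser rule 8 columns matched more than 1 library each, and the other 4 matched 1 library each. All 12 columns shared every library they matched with another column.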
